A study of Mus musculus with 9 samples.

How the data were processed

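RNA from the heart apex of male wild-type C57BL/6J mice was sequenced. Per the labels' protocols, the mice received an intramuscular injection of 1e+11 viral particles of adeno-associated virus (AAV) into the right gastrocnemius at 10 weeks of age and the heart was collected 12 weeks later. AAV-Osm carries the gene of the cytokine oncostatin M, and AAV-Null is the control vector. The labels name 5 samples per group as submitted for sequencing; 9 libraries were analysed here, 4 AAV-Null and 5 AAV-Osm, and the fifth AAV-Null sample was not analysed here. The labels list each library as its own sample without stating outright that each came from a different mouse, so p-values measure the spread between these 9 samples. Libraries carry no replicate number in the labels, were numbered within each group as names only, and were not paired.

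Per the labels' protocols, mRNA was enriched, libraries were prepared with a KAPA mRNA HyperPrep kit and read as 75 base paired ends. Per the submitters' processing notes, STAR 2.5.2b, featureCounts and Subread 1.5.1 were used with the mouse genome build mm10. The gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. The deposited values are raw counts per gene: whole numbers whose totals differ between libraries. The deposited table holds 13192 named genes with their mm10 coordinates and summed exon length, and 4141 blank lines that hold no values and were left out. All 13192 genes had more than 0.5 CPM (counts scaled to a common library size) in at least 4 libraries, so genes below that level were not analysed here. The transgene's own gene, Osm, was not analysed here, so the delivered transcript could not be used to check the labels, and neither was Reg3b or any of the genes of the mitochondrial genome (0 listed).

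Total counts over the named genes ran from 11841106 to 30625134 per library. Before replicates were averaged, all pairs of libraries were compared by a chi-square statistic over genes with at least 10 counts in the pair. The smallest value per degree of freedom was 6.52, and 0 pairs held identical values, so each library was counted as its own sample. The statistic cannot show whether libraries came from different mice. Its smallest value was for AAV-Null 1 with AAV-Null 2, while the other AAV-Null pairs ran from 45.0 to 98.1. AAV-Osm 2 with AAV-Osm 3 was at 9.68, and the other AAV-Osm pairs ran from 30.1 to 85.9. Why these pairs lay closer was not tested.

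The comparison was AAV-Osm against AAV-Null, with group as the only term. Counts were tested with edgeR 4.0.16 in R 4.3.3 by the two-sided quasi-likelihood F test with robust dispersion estimates, after TMM scaling. The filterByExpr step removed 0 genes. P-values were adjusted by the Benjamini-Hochberg method over the 13192 genes, and an adjusted p under 0.05 was the threshold. CPM values are scaled by the TMM factors, with SD between libraries, and log2 fold changes are AAV-Osm over AAV-Null with their standard error (SE). On simulated counts for the 13192 genes of this comparison, the test recovered 9 of 50 genes changed by 1.5-fold, 32 of 50 changed by 2-fold, 49 of 50 changed by 3-fold and 48 of 50 changed by 4-fold; 10 of its 148 calls were unchanged genes.

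Gene lists for pathways and cell types, 58 in all, were fixed before the data were examined, as were the test, the first set of alternatives and the rule for naming genes. Of these lists, 55 had at least 5 members among the genes tested and were compared with all other genes by limma 3.58.1's camera test with a preset correlation of 0.01, adjusted over the 55 lists. For each list the members past the threshold were counted over all genes and again adjusted over the list alone. The camera test with an estimated correlation and fry, which asks whether a list's genes move on balance in a single direction or (its mixed form) in either direction, were alternatives. A list's mean log2 CPM per library (prior count 2) was compared between the groups by an exact two-sided permutation test over all 126 regroupings, whose smallest possible p is 0.0159. The same exact test was used for the measures of library composition.

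The naming rule took a fixed set of genes tied to oncostatin M signalling, fibrosis and heart muscle, the 12 genes with the largest change in each direction among those past the threshold with a mean of at least 1 CPM in the higher group and no overlap between groups, up to 4 members past the threshold per described list (or the 2 most abundant where none passed), and the 5 genes with the smallest p in each direction. Genes named because they passed adjusted over a list alone, with all libraries or without a pair of them, the other clock genes named in the closing section, and Txnip fall outside that rule and were chosen after their values were seen. A gene that passed adjusted over a list alone and a member of the clock list are not reported here.

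Alternatives fixed beforehand were DESeq2's size factors, upper-quartile factors or total counts in place of TMM, erythroid genes left out, a minimum mean of 1 CPM, the Wald test of DESeq2 1.42.0, limma-voom without and with sample quality weights, dispersion estimates that are not robust, 1 surrogate variable from sva 3.50.0, an adjusted p under 0.01, a minimum fold of 1.5, and each library left out in turn. Chosen after seeing the data were leaving out Rn45s (the gene of the ribosomal RNA precursor), offsets from a smooth trend on exon length and GC content, and leaving out either AAV-Null 4 with AAV-Osm 5 or AAV-Null 3 with AAV-Null 4. GC content came from a GENCODE M21 annotation and sequence of mm10 matched by symbol, which covered 12718 genes (96.4%). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.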

Results

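The data were RNA-seq read counts from 9 heart apex samples of mice injected in a leg muscle, 4 with a control vector (AAV-Null) and 5 with a vector carrying oncostatin M (AAV-Osm). Oncostatin M is a cytokine of the interleukin-6 family that signals through receptors containing gp130, the product of Il6st. Total counts were 18594875, 22703288, 30625134 and 22150733 in AAV-Null 1 to 4 and 24551980, 19773378, 16634863, 11841106 and 19113143 in AAV-Osm 1 to 5. The comparison asked how the heart's transcripts differed 12 weeks after the injection, in a study concerned with cardiac dysfunction, muscle wasting and fibrosis under added oncostatin M.

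Few genes differed between the groups. Those past the threshold included receptor, metabolic, clock and inflammatory genes, and 0 collagen or natriuretic peptide genes passed in edgeR. The genes of the beta chains of the interleukin-3 receptor family, Csf2rb and Csf2rb2, were 7.70-fold and 3.90-fold higher in AAV-Osm hearts. The muscle uncoupling protein gene Ucp3 was 4.41-fold higher, Angptl4, whose product inhibits lipoprotein lipase, was 4.28-fold higher, and the clock output genes Dbp and Ciart were 2.77-fold and 3.39-fold higher. The monocyte chemokine gene Ccl2, the cell cycle inhibitor gene Cdkn1a and the water channel gene Aqp1 were 2.56-fold, 2.34-fold and 1.73-fold lower. In edgeR's test 16 of 13192 genes passed the adjusted threshold, 11 higher and 5 lower, and in all 16 no AAV-Osm library overlapped an AAV-Null library. The labels give no collection times, so a different time of day at collection cannot be excluded for any of these genes.

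At an unadjusted p under 0.05, edgeR gave 788 genes, 381 higher and 407 lower, where 659.6 would be given by chance. The groups did not overlap for 301 genes (139 higher, 162 lower), 2.28% of those tested, where chance gives 1.59%. Of the 22 genes tested among those the naming rule always includes, 0 passed in edgeR or DESeq2 and 4 with limma-voom and quality weights, Nppb (log2 fold change -1.15), Il6st (0.66), Fbxo32 (0.53) and Serpina3n (1.01). DESeq2 called 53 genes and limma-voom with quality weights 170. Csf2rb, Rasa4, Scgb3a1 and Ucp3 passed with each library left out in turn, and the other 12 calls were lost without at least 1 library. Among the 9 fits that each left out 1 library, the Ccl2 call was lost in 2, those of Angptl4, Ciart and Aqp1 in 6, those of Dbp, Cdkn1a and Mtl5 in 7, those of C4b, Ddit4, Tubb2b and Selp in 8 and that of Csf2rb2 in 9. The count of changed genes was 5, 4, 11 and 10 without AAV-Null 1, 2, 3 and 4, and 6, 4, 7, 9 and 8 without AAV-Osm 1, 2, 3, 4 and 5.

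Csf2rb (chromosome 15, 78325990 to 78351001, plus strand, mm10) had the smallest p. It rose from 2.17 ± 0.276 CPM (SD, n = 4) to 16.6 ± 2.15 CPM (SD, n = 5), a log2 fold change of 2.94 (SE 0.17, edgeR adjusted p = 3.62e-06). Csf2rb2 lies beside it on the minus strand (15, 78282508 to 78305721) and rose from 1.03 ± 0.257 to 3.96 ± 1.75 CPM (log2 fold change 1.96, SE 0.33, edgeR adjusted p = 0.0424). The paralogs are close in sequence, so reads shared between them leave the split of the change uncertain, and the Csf2rb2 call was lost with each of the 9 libraries left out. Rasa4 (5, 136083916 to 136111861, plus strand), which encodes a Ras GTPase-activating protein, rose by 1.93 on the log2 scale (SE 0.18, edgeR adjusted p = 0.000358), from 7.24 ± 1.24 to 27.5 ± 4.61 CPM. Scgb3a1 (11, 49663595 to 49665118, plus strand), a secreted secretoglobin, rose by 3.07 (SE 0.37, edgeR adjusted p = 0.00496) but from a low level, 0.327 ± 0.121 to 2.76 ± 1.25 CPM, with AAV-Osm 5 at 4.99 CPM and the other AAV-Osm libraries at 2.09 to 2.31. Mtl5 (19, 3388857 to 3407823, plus strand) rose from 1.72 ± 0.619 to 5.53 ± 1.04 CPM (log2 fold change 1.66, SE 0.25, edgeR adjusted p = 0.0325).

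**Figure D1:**
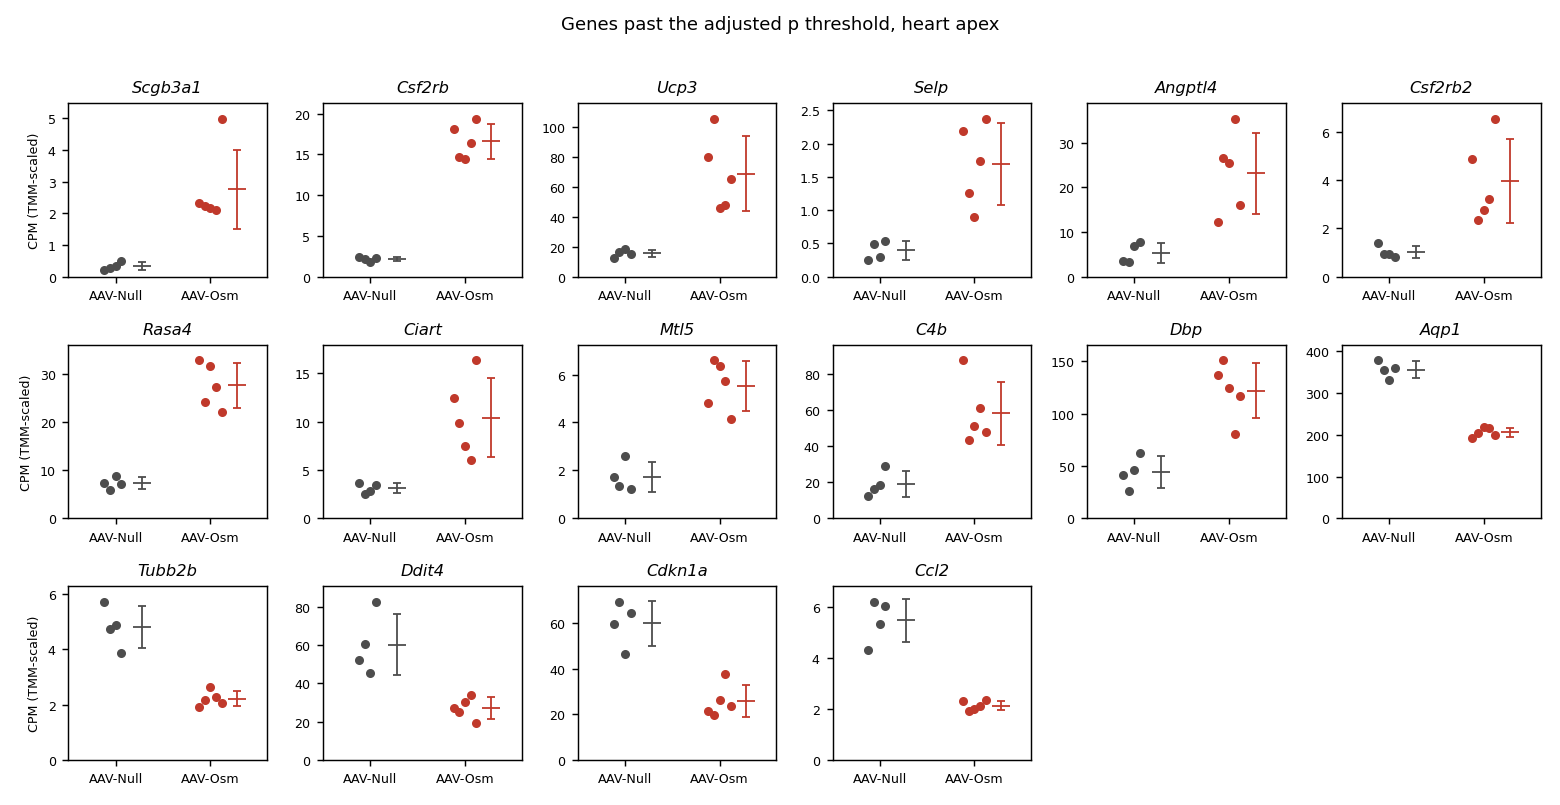
TMM-scaled CPM (vertical axes, from 0) of the 16 genes past the edgeR threshold in each AAV-Null (grey, n = 4) and AAV-Osm (red, n = 5) library, with the mean and SD beside the points. For Csf2rb the AAV-Null libraries lie between 1.78 and 2.41 CPM and the AAV-Osm libraries between 14.4 and 19.4 CPM.

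Of 45 tested genes for fatty acid uptake and oxidation, 2 rose and 0 fell over all genes, and 43 did not pass. Ucp3 (7, 100472991 to 100486432, plus strand) rose from 15.6 ± 2.48 to 69.0 ± 24.9 CPM (log2 fold change 2.14, SE 0.25, edgeR adjusted p = 0.00358). Angptl4 (17, 33774900 to 33781575, minus strand) rose from 5.35 ± 2.27 to 23.1 ± 9.14 CPM (log2 fold change 2.10, SE 0.34, edgeR adjusted p = 0.0369). Adjusted over the list alone, 3 genes were higher and 0 lower, the added gene being Lipe, hormone-sensitive lipase (log2 fold change 0.44, SE 0.12). Ucp3 and Angptl4 still passed so without AAV-Null 4 and AAV-Osm 5 and without AAV-Null 3 and AAV-Null 4, but Lipe did not. In the latter case another member passed in its place. The list's median log2 fold change was 0.08 and its camera adjusted p was 0.00401, but the adjusted p = 0.326 with an estimated correlation. Without AAV-Null 4 and AAV-Osm 5 the camera adjusted p was 0.0892; over the alternatives it ran from 0.000347 to 0.326. Ppargc1a, a coactivator of mitochondrial genes, had a log2 fold change of 0.02 (SE 0.18), and Cpt1b, the muscle carnitine palmitoyltransferase, one of 0.37 (SE 0.37) at 1.76 ± 0.837 and 2.29 ± 0.831 CPM. Cpt1b overlaps a neighbouring locus in the annotation and its counts are uncertain. The Angptl4 call was lost without AAV-Null 1, 2 or 3 or AAV-Osm 2, 3 or 4.

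The core circadian clock list held 19 tested genes, of which 2 rose, 0 fell and 17 did not pass over all genes. Dbp (7, 45705247 to 45710203, plus strand), a transcription factor driven by the clock, rose from 44.1 ± 15.0 to 122 ± 26.3 CPM (log2 fold change 1.47, SE 0.24, edgeR adjusted p = 0.0369). Ciart (3, 95878505 to 95882228, minus strand), a repressor of clock transcription, rose from 3.10 ± 0.528 to 10.4 ± 4.11 CPM (log2 fold change 1.76, SE 0.28, edgeR adjusted p = 0.0349). Adjusted over the list alone, 6 genes were higher (Dbp, Ciart, Per1, Per3, Tef and Cry2) and 2 were lower (Arntl and Nfil3). With AAV-Null 4 and AAV-Osm 5 left out these were 4 higher (Dbp, Ciart, Per1 and Tef) and 4 lower (Arntl, Nfil3, Cry1 and Npas2), and without AAV-Null 3 and AAV-Null 4 they were 3 higher (Dbp, Ciart and Per1) and 3 lower (Arntl, Nfil3 and Cry1). Arntl, the partner of CLOCK in the activating complex, had a log2 fold change of -1.19 (SE 0.25, edgeR adjusted p = 0.186 over all genes), and Nfil3, which opposes Dbp at the same DNA elements, one of -0.90 (SE 0.19, edgeR adjusted p = 0.199). Per1 had a log2 fold change of 0.61 (SE 0.13, edgeR adjusted p = 0.171). The list's median was 0.39 (0.25 and 0.11 without these pairs of libraries in turn) with a camera adjusted p of 0.000109, but the adjusted p = 0.326 with an estimated correlation. The list mean had an exact permutation p of 0.127, a test in which members that rose and fell offset each other. In fry's mixed test, which allows both directions, the adjusted p was 0.00258. Dbp and Ciart passed over all genes and may carry that value alone, so it says little about the other members. The camera adjusted p was 0.265 without AAV-Null 4 and AAV-Osm 5 and 0.524 without AAV-Null 3 and AAV-Null 4; over the alternatives it ran from 5.44e-07 to 0.524.

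**Figure D2:**
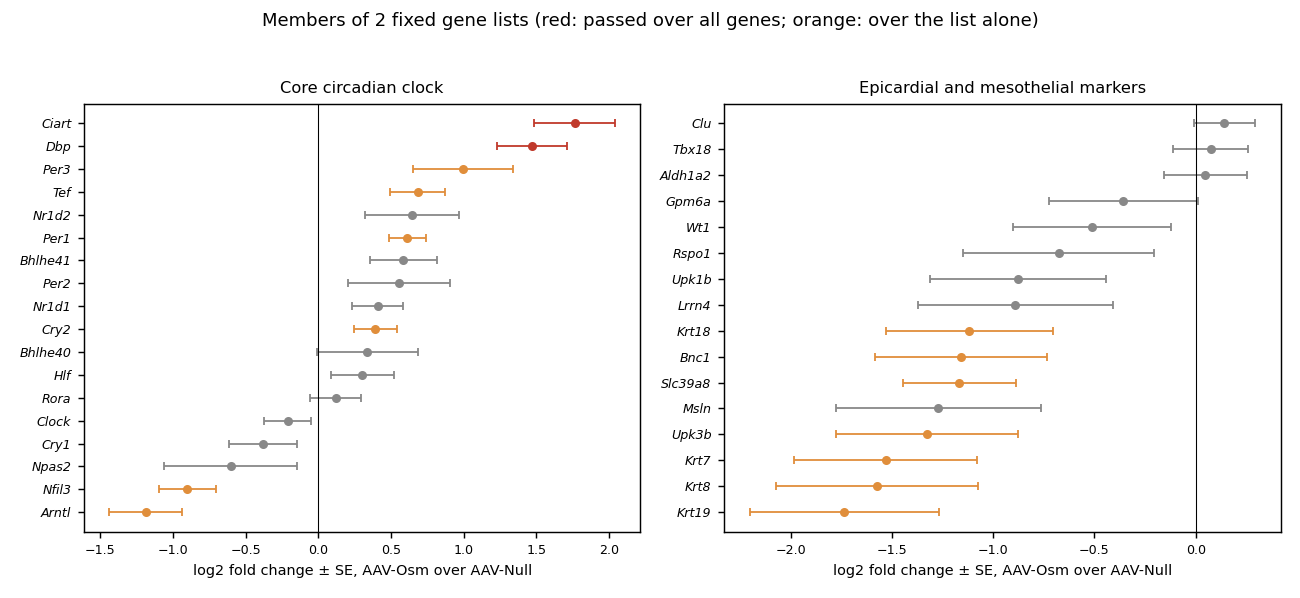
Log2 fold change (horizontal axes, AAV-Osm over AAV-Null, bars are SE) of 18 of the 19 clock genes and the 16 epicardial and mesothelial markers tested, with red for genes past the threshold over all genes, orange for those past it over the list alone and grey for the rest. Clock genes run from -1.19 for Arntl to 1.76 for Ciart, and 13 of the 16 epicardial markers lie below 0.

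Among 22 chemokine and leukocyte recruitment genes, 1 rose, 1 fell and 20 did not pass over all genes. Ccl2 (11, 82035577 to 82037452, plus strand) fell by 1.35 on the log2 scale (SE 0.18, edgeR adjusted p = 0.0116), from 5.46 ± 0.848 to 2.12 ± 0.189 CPM. Selp (1, 164115264 to 164150026, plus strand), the endothelial and platelet adhesion receptor P-selectin, rose by 2.11 (SE 0.36, edgeR adjusted p = 0.0499) at a low level, from 0.395 ± 0.142 to 1.69 ± 0.621 CPM. That call lay at the threshold and was lost in 15 of its 23 alternatives (adjusted p 0.000286 to 0.238), including 8 of the 9 libraries left out in turn, both pairs of libraries left out, upper-quartile factors, total counts, limma-voom without weights, dispersions that are not robust, and length and GC offsets. Adjusted over the list alone, 2 genes were higher (Selp and Ackr1) and 2 lower (Ccl2 and Cxcl9), and Cxcl9, an interferon-induced chemokine, had a log2 fold change of -1.0 (SE 0.25). The list's median was -0.23 with a camera adjusted p of 0.0146, but the adjusted p = 0.515 with an estimated correlation, and fry's mixed test gave an adjusted p of 2.38e-05. Ccl2 and Selp may carry that mixed value. Without AAV-Null 4 alone the camera adjusted p was 0.289; over the alternatives it ran from 0.000221 to 0.627.

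Of 27 complement and coagulation genes, 1 rose, 0 fell and 26 did not pass. C4b (17, 34728381 to 34743897, minus strand), a complement component, rose from 19.0 ± 7.23 to 58.3 ± 17.6 CPM (log2 fold change 1.62, SE 0.26, edgeR adjusted p = 0.0369). Its near-identical neighbour C4a was not analysed here, and reads shared with it leave the C4b value uncertain. Adjusted over the list alone, 3 genes were higher, C4b and Cfb among them, and 1 was lower (F10). Leaving out AAV-Null 4 and AAV-Osm 5 gave 7 higher and 4 lower, F10 not among them, and leaving out AAV-Null 3 and AAV-Null 4 gave 3 higher (C4b, Cfb and Vwf, the von Willebrand factor gene) and 0 lower. Cfb, complement factor B, had a log2 fold change of 1.24 (SE 0.34). The camera adjusted p of the list was 0.661, 0.159 without AAV-Null 4 and AAV-Osm 5, and without AAV-Null 3 and AAV-Null 4 it was called upward at 0.0289 (0.0250 to 0.997 over the alternatives). Of 18 acute-phase genes 0 rose and 0 fell over all genes; adjusted over the list alone, 3 were higher (Serpina3n, Serpina3g and Cfb). Serpina3n had a log2 fold change of 0.85 (SE 0.24, edgeR adjusted p = 0.490) and belongs to a family of similar genes, so its counts are uncertain. The acute-phase list was called upward (median 0.07, camera adjusted p = 0.0270), but the adjusted p = 0.515 with an estimated correlation. Of its tested members 4 also stand in a list of liver-type genes, whose transcripts summed highest in AAV-Null 3 and AAV-Null 4 (369 and 212 CPM). Without these libraries the acute-phase median was 0.83, its camera adjusted p was 8.39e-06, and 6 members were higher adjusted over the list alone, C3, Hp and Itih4 being added (log2 fold changes 0.98, 1.61 and 2.09 there, 0.13, 0.18 and 0.67 with all libraries). The liver-type sums that remained were 21.5 and 69.4 CPM in AAV-Null and 17.5 to 142 CPM in AAV-Osm. The rise without these libraries thus cannot be told apart from liver-type RNA in AAV-Osm libraries. Without AAV-Null 1 the camera adjusted p was 0.671; over the alternatives it ran from 8.39e-06 to 0.671.

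The muscle atrophy and ubiquitin ligase list had 38 tested genes, of which 0 rose, 2 fell and 36 did not pass, and the same 2 passed adjusted over the list alone. Cdkn1a (17, 29090986 to 29100722, plus strand) fell by 1.23 on the log2 scale (SE 0.19, edgeR adjusted p = 0.0331), from 59.9 ± 9.84 to 25.7 ± 7.01 CPM. Ddit4 (10, 59949675 to 59951770, minus strand), a stress-induced inhibitor of mTOR signalling, fell by 1.15 (SE 0.19, edgeR adjusted p = 0.0427), from 60.1 ± 16.1 to 27.1 ± 5.49 CPM. The ubiquitin ligase genes Fbxo32 and Trim63 had log2 fold changes of 0.46 (SE 0.14, edgeR adjusted p = 0.552) and -0.05 (SE 0.16). Eda2r, a TNF-family receptor gene, had one of 0.04 (SE 0.25) at 1.43 ± 0.365 and 1.46 ± 0.282 CPM. The list's median was 0.03, its mean was -0.01 and its camera direction was downward with an adjusted p of 0.973, turning under some alternatives. Cdkn1a and Ddit4 also stand in the list of glucocorticoid-responsive genes, where 1 of 21 tested rose (Angptl4), 2 fell and 18 did not pass. Adjusted over that list alone, 2 were higher (Per1 and Angptl4) and 3 lower (Cdkn1a, Ddit4 and Errfi1). The glucocorticoid list's camera adjusted p was 0.136 and with 1 surrogate variable 0.0328 (0.0179 to 0.515 over the alternatives), and fry's mixed test gave 9.86e-06. Angptl4, Cdkn1a and Ddit4, past the threshold over all genes, may carry that mixed value.

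For the oncostatin M receptor complex and cytokine family, 0 of 12 tested genes passed, over all genes or adjusted over the list alone, and the camera adjusted p was 0.274. Osmr, the specific receptor chain, was at 6.75 ± 1.39 CPM in AAV-Null and 12.2 ± 4.33 CPM in AAV-Osm hearts (log2 fold change 0.86, SE 0.25, edgeR adjusted p = 0.497). Il6st had a log2 fold change of 0.52 (SE 0.19, edgeR adjusted p = 0.648) and Lifr, the leukemia inhibitory factor receptor, one of 0.29 (SE 0.16). Of 32 gp130-STAT3 target genes 0 passed either way, with Socs3, the feedback inhibitor, at 0.54 (SE 0.22, edgeR adjusted p = 0.779), Stat3 at -0.25 (SE 0.20) and Timp1 at -0.27 (SE 0.26). Of these targets 1 was higher adjusted over the list alone without AAV-Null 4 and AAV-Osm 5 (Il4ra) and 1 without AAV-Null 3 and AAV-Null 4 (Serpina3n). The target list's median was -0.05, its mean was 0.02 and its camera direction was upward with an adjusted p of 0.803, turning under some alternatives.

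Fibrosis genes did not pass over all genes. Of 20 fibrillar and basement-membrane collagens 0 rose and 0 fell, over all genes or adjusted over the list alone, and 18 had a negative log2 fold change. Col1a1 had one of -0.32 (SE 0.17, edgeR adjusted p = 0.883), Col3a1 one of -0.21 (SE 0.17) and Col4a1 one of -0.13 (SE 0.18). The collagen list's median was -0.28 and it was called downward (camera adjusted p = 6.14e-05), but the adjusted p = 0.416 with an estimated correlation. Without AAV-Null 4 and AAV-Osm 5 its camera adjusted p was 0.172; over the alternatives it ran from 2.80e-07 to 0.416. Of 26 fibroblast markers 0 passed over all genes and 1 was lower adjusted over the list alone, Meox1 (log2 fold change -0.54, SE 0.14). Dcn, an abundant fibroblast proteoglycan gene, had a log2 fold change of -0.27 (SE 0.22). The fibroblast list was called downward (camera adjusted p = 0.00377), but the adjusted p = 0.515 with an estimated correlation, and it was 0.348 in camera without AAV-Null 4; over the alternatives it ran from 0.000129 to 0.630. Of 18 myofibroblast markers 0 passed over all genes and 1 was lower adjusted over the list alone, again Meox1, with Postn at 0.02 (SE 0.29), Acta2 at -0.38 (SE 0.22) and a camera adjusted p of 0.178, which was 0.0189 and downward without AAV-Null 3 and AAV-Null 4 (0.0189 to 0.530 over the alternatives). Of 39 matrix proteases, inhibitors and crosslinkers 0 passed over all genes and 1 was lower adjusted over the list alone, Serpinh1, the chaperone of collagen folding. Serpinh1 was at 299 ± 14.2 CPM in AAV-Null and 204 ± 20.1 CPM in AAV-Osm hearts (log2 fold change -0.55, SE 0.12, edgeR adjusted p = 0.229), the groups did not overlap, and it passed in DESeq2 and in limma-voom with quality weights. The matrix list was called downward (median -0.15, camera adjusted p = 0.00389), but the adjusted p = 0.326 with an estimated correlation. Its camera adjusted p was 0.134 without AAV-Null 4, 0.464 without AAV-Null 4 and AAV-Osm 5 and 0.232 without AAV-Null 3 and AAV-Null 4; over the alternatives it ran from 0.000762 to 0.464.

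In the cardiac stress and fetal gene programme 0 of 29 genes passed, over all genes or adjusted over the list alone. Nppa and Nppb, the natriuretic peptide genes, had log2 fold changes of 0.34 (SE 0.26, edgeR adjusted p = 0.936) and -0.67 (SE 0.34, edgeR adjusted p = 0.873). With limma-voom and quality weights Nppb passed at -1.15 (adjusted p = 0.0371; 0.0371 to 1 over the alternatives). In the stress list 3 genes were lower adjusted over the list alone without AAV-Null 4 and AAV-Osm 5 (Nppb, Gdf15 and Nmrk2) and 1 without AAV-Null 3 and AAV-Null 4 (Nmrk2). Myh7, the slow myosin heavy chain, was at 97.7 ± 22.4 and 168 ± 77.1 CPM (log2 fold change 0.78, SE 0.33, edgeR adjusted p = 0.796), and Acta1 had a log2 fold change of 0.15 (SE 0.33). The stress list's median was 0.05, its mean was -0.03 and its camera direction was upward with an adjusted p of 0.96, turning under some alternatives. Of 34 genes of the mature contractile apparatus 0 passed either way and 27 had a positive log2 fold change, Myh6 among them (0.20, SE 0.18). Leaving out AAV-Null 4 and AAV-Osm 5 gave 1 gene higher adjusted over the list alone (Tcap), and leaving out AAV-Null 3 and AAV-Null 4 gave 2 (Tcap and Myom3). That list was called upward (median 0.12, camera adjusted p = 0.00179), but the adjusted p = 0.326 with an estimated correlation. With 1 surrogate variable its camera adjusted p was 0.0611; over the alternatives it ran from 0.000129 to 0.326. Atp2a2, the sarcoplasmic calcium pump, had a log2 fold change of 0.23 (SE 0.18).

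Of 23 dedifferentiation and remodelling genes linked to oncostatin M in cardiomyocytes, 0 rose, 1 fell and 22 did not pass. Tubb2b (13, 34127008 to 34130354, minus strand), a beta-tubulin, fell by 1.13 on the log2 scale (SE 0.19, edgeR adjusted p = 0.0421), from 4.80 ± 0.759 to 2.21 ± 0.271 CPM. Tubulin genes are close in sequence and the value is uncertain where reads are shared. Adjusted over the list alone, 0 were higher and 2 lower, the added gene being Nes, the intermediate filament gene nestin (log2 fold change -0.80, SE 0.18), and Runx1 had a log2 fold change of 0.04 (SE 0.24). This list was called downward (median -0.10, camera adjusted p = 0.00377), but the adjusted p = 0.276 with an estimated correlation. Its members Krt8 and Krt18 are also epicardial and mesothelial markers, which had a median of -1.0. Among 26 endothelial markers 0 rose, 1 fell and 25 did not pass, and the same gene passed adjusted over the list alone. Aqp1 (6, 55336299 to 55348555, plus strand) fell by 0.79 on the log2 scale (SE 0.11, edgeR adjusted p = 0.0245), from 356 ± 19.6 to 206 ± 10.5 CPM. The endothelial list was called downward (median -0.11, camera adjusted p = 0.00554), but the adjusted p = 0.326 with an estimated correlation, and it was 0.118 in camera without AAV-Null 4; over the alternatives it ran from 0.00109 to 0.326.

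Epicardial and mesothelial markers, genes of the cell layer on the heart's surface, had the smallest camera p of the 55 lists tested. Of 16 tested, 0 passed over all genes, while 0 were higher and 7 lower adjusted over the list alone (Upk3b, Krt7, Krt8, Krt18, Krt19, Bnc1 and Slc39a8). Krt19 was at 9.91 ± 6.61 CPM in AAV-Null and 2.98 ± 1.46 CPM in AAV-Osm hearts (log2 fold change -1.73, SE 0.47, edgeR adjusted p = 0.468), and Upk3b, a mesothelial uroplakin, at 29 ± 18.1 and 11.5 ± 6.14 CPM (log2 fold change -1.33, SE 0.45, edgeR adjusted p = 0.622). Clu, the most abundant member, had a log2 fold change of 0.14 (SE 0.15). The list was called downward (median -1.0, camera adjusted p = 4.23e-10), but the adjusted p = 0.310 with an estimated correlation. The mean over the list was lower in every AAV-Osm library (highest 2.29 log2 CPM) than in every AAV-Null library (lowest 2.33), an exact permutation p of 0.0159, the smallest 126 regroupings can give. Keratins were high in AAV-Null 3 and AAV-Null 4, the libraries with the largest sums of liver-type transcripts (369 and 212 CPM). Krt8 was at 6.12 and 6.41 CPM there, at 1.25 and 1.52 CPM in AAV-Null 1 and AAV-Null 2 and at 0.522 to 1.99 CPM in AAV-Osm. Without AAV-Null 3 and AAV-Null 4 the log2 fold change of Krt8 went from -1.57 to -0.11, that of Krt18 from -1.12 to -0.28, that of Krt7 from -1.53 to -0.46, that of Krt19 to -0.77 and that of Upk3b to -0.71, while Bnc1 stood at -1.31 and Slc39a8 at -1.29. The 7 genes lower adjusted over the list alone became 1 (Slc39a8) without these libraries and 3 (Krt19, Slc39a8 and Wt1) without AAV-Null 4 and AAV-Osm 5. The list stayed called in camera in both cases (adjusted p 0.00241 and 0.00107); over the camera alternatives the adjusted p ran from 6.10e-14 to 0.310. Keratin genes have processed copies elsewhere in the genome, so their counts are uncertain where reads match several places.

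Several lists were called with small shifts and 0 members past the threshold over all genes. Of 65 cytosolic ribosomal protein genes 60 had a negative log2 fold change and 0 passed either way (median -0.19, camera adjusted p = 6.14e-05), but the adjusted p = 0.701 with an estimated correlation. Without AAV-Null 3 and AAV-Null 4 their direction turned upward (median 0.18, camera adjusted p = 0.000178). Leaving out AAV-Null 4 alone was enough to turn it (median 0.040, camera adjusted p = 0.664), as was leaving out AAV-Null 4 and AAV-Osm 5 (0.10, 0.141), and over the camera alternatives the adjusted p ran from 3.18e-12 to 0.701. Heat shock and chaperone genes (19 tested, 0 passed either way, median -0.20) had a camera adjusted p of 0.000109, and the adjusted p = 0.276 with an estimated correlation. Of these genes 3 were lower adjusted over the list alone without AAV-Null 4 and AAV-Osm 5 (Dnaja1, Dnajb4 and Hsp90aa1; list median -0.27) and 5 without AAV-Null 3 and AAV-Null 4 (Dnaja1, Hsp90aa1, Hspa1b, Hspb1 and Hsph1; list median -0.30). With all libraries Dnaja1 and Hsp90aa1 had log2 fold changes of -0.64 (SE 0.18) and -0.54 (SE 0.18), and Cryab, an abundant member, one of -0.06 (SE 0.15). Of 28 unfolded protein response genes 0 passed over all genes and 1 was lower adjusted over the list alone, Sdf2l1 (log2 fold change -0.74, SE 0.18), which became 4 without AAV-Null 4 and AAV-Osm 5 (Hyou1, Manf and Pdia4 added) and 0 without AAV-Null 3 and AAV-Null 4; the camera adjusted p was 0.000805, and the adjusted p = 0.326 with an estimated correlation. In all, camera called 23 of 55 lists, 5 upward and 18 downward, and 0 were called with an estimated correlation (adjusted p 0.276 to 0.751) or by fry, while fry's mixed test called 11. Every list called by the mixed test held a gene past the threshold over all genes, so single members may carry it. Other splits of the libraries, which mixed the groups (closing section), gave 2 to 29 lists in camera. A camera adjusted p with the preset correlation therefore does not by itself show a difference between the groups. By the exact permutation test of the list mean, not adjusted over lists, p ran from 0.0159 to 0.683 over these 23 lists. Without AAV-Null 4 and AAV-Osm 5 the camera count was 8.

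The measures of library composition did not separate the groups. Total counts (exact permutation p = 0.175), the share of counts in the 10 most abundant genes (0.286 by the same exact test), genes detected (0.683) and the share in erythroid genes (1) overlapped between groups, with adjusted values of 0.476 or more. Rn45s, the ribosomal RNA precursor gene, took 8.07% to 15.6% of counts (exact permutation p = 0.317). Liver-type transcripts, 29 genes listed after the data had been looked at, summed to 21.5, 69.4, 369 and 212 CPM in AAV-Null 1 to 4 and 85.3, 17.5, 142, 78.4 and 44.9 CPM in AAV-Osm 1 to 5 (exact permutation p = 0.286). The first principal component of log2 CPM held 35.6% of the variance and did not follow the groups (exact permutation p = 0.667), and AAV-Null 4 and AAV-Osm 5 lay at its opposite ends.

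**Figure D3:**
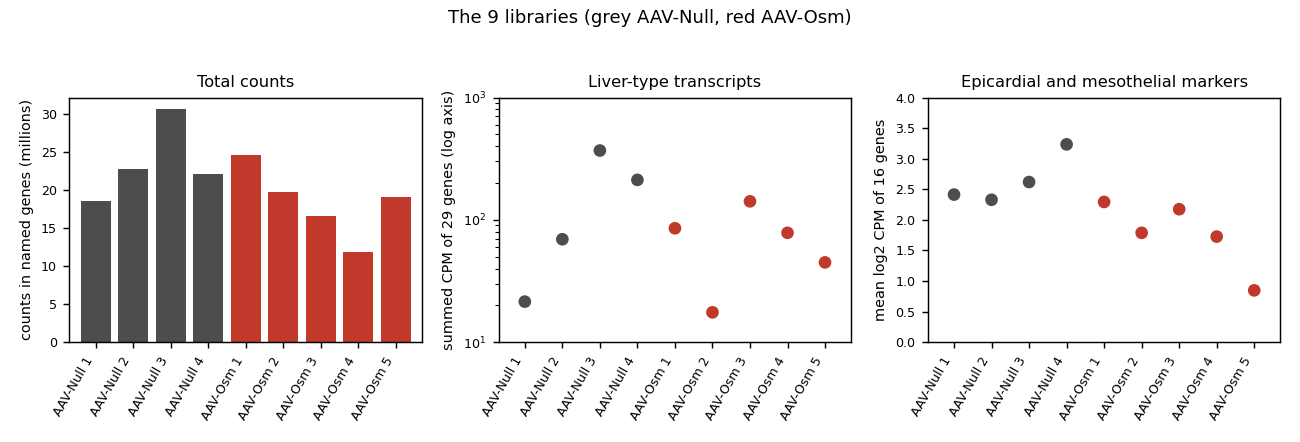
Total counts (bars, left), summed CPM of 29 liver-type genes (points, log axis, middle) and mean log2 CPM of 16 epicardial and mesothelial markers (points, right) in each of the 4 AAV-Null (grey) and 5 AAV-Osm (red) libraries. Total counts run from 11841106 to 30625134, the liver-type sum from 17.5 to 369 CPM, and the epicardial mean is lowest in AAV-Osm 5 (0.847) and highest in AAV-Null 4 (3.23).

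Simulated counts of this size, drawn for each gene independently with its fitted dispersion, recovered 18% of genes changed by 1.5-fold and 64% of those changed by 2-fold. Smaller changes could thus be missed at this number of samples. The simulation lacks the leading component shared by many genes, so recovery in the data may be lower. The 95% interval of the log2 fold change was -0.68 to 0.05 for Col1a1, -0.24 to 0.91 for Nppa and 0.32 to 1.41 for Osmr, each before adjustment over genes.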

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

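The measure that marked a library was fixed in advance, and the tests on the epicardial markers were chosen after the result was seen. A library was marked when its log2 CPM lay far from the rest of its group, measured as its gap to the nearest other library over the group's whole range. Among 100 genes and 6 measures of the libraries, 212 groups were looked at, 8 held such a library, and chance alone marks about 10.6.

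Scgb3a1 was at 4.99 CPM in AAV-Osm 5 and at 2.09 to 2.31 in the other AAV-Osm libraries (gap over range 0.885). Col1a1 was at 58.1 CPM in AAV-Null 3 and at 82.0 to 87.4 in the other AAV-Null libraries (0.845). Eda2r was at 0.958 CPM in AAV-Osm 4 and at 1.51 to 1.63 in the others of its group (0.855). Serpinh1 was at 278 CPM in AAV-Null 4 and at 305 to 309 in the other AAV-Null libraries (0.888). Of the clock genes, Rora was at 60.6 CPM in AAV-Osm 4 and at 36.3 to 40.9 in the other AAV-Osm libraries (0.771), and Bhlhe40 at 13.1 CPM in AAV-Null 4 and at 23.7 to 26.5 in the other AAV-Null libraries (0.844).

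The other marked values were both epicardial markers. Krt19 was at 0.665 CPM in AAV-Osm 5 against 2.67 to 4.38 in the other AAV-Osm libraries (0.728), and Upk3b at 56.0 CPM in AAV-Null 4 against 18.6 to 22 in the other AAV-Null libraries (0.845). The list of 16 epicardial and mesothelial markers was lower in AAV-Osm by 0.88 log2 CPM on average (difference -0.88), with the exact permutation p at its smallest value. That value was reached by 2 of 57 lists, where 0.905 would by chance. The other was the dedifferentiation list, which shares Krt8 and Krt18 with the epicardial list, so the 2 are not independent. The tables argue against a trend on gene length and GC content as the cause, since the difference after correction was 0.994 of that before. They do not settle how far a pair of libraries carries it. Without AAV-Null 4 and AAV-Osm 5, at the ends of the leading component, the difference was -0.46, or 0.519 of its size (exact permutation p = 0.0571). Without AAV-Null 3 and AAV-Null 4, which hold the most liver-type RNA and the most keratin transcripts, it was -0.61, or 0.685 of its size (exact permutation p = 0.0952). Each p is the smallest that the remaining libraries can give. The list mean separated the groups with all libraries, so these p-values were fixed in advance. A smaller difference was built in too. AAV-Null 4 had the highest list mean of all libraries and AAV-Osm 5 the lowest, and AAV-Null 3 and AAV-Null 4 had the highest of their group. Within groups the markers moved together (median pairwise correlation of deviations 0.447, highest of 1000 random lists of matched expression 0.285). A smaller share of surface tissue in the AAV-Osm samples, through dissection or through the treatment, could give this. Regulation shared by these genes could give the same and stays open. AAV-Null 4 (list mean 3.23 log2 CPM) and AAV-Osm 5 (0.847) lay farthest from the other libraries of their groups. They may carry much of this correlation, which was not computed without them.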

How the results depend on the processing

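The length and GC offsets, leaving out Rn45s and leaving out a pair of libraries were chosen after the data were seen; the other alternatives and leaving out each library in turn were fixed before. The alternative with no filter on low counts was void, since the filter removed 0 genes, and gave no values. All 16 genes past the threshold kept their direction under every alternative run. Their libraries did not overlap between the groups, so leaving libraries out could hardly turn a direction and is no test of it. Of 224 values from alternatives other than leaving out 1 library, 200 stayed past the threshold and 24 did not, and of 144 values with 1 library left out 62 stayed and 82 did not. Those 24 were Csf2rb2, Ciart, Selp and Tubb2b with total counts, Csf2rb2, Selp and Ddit4 with limma-voom, Selp with upper-quartile factors, with dispersions that are not robust and with length and GC offsets, Angptl4 with 1 surrogate variable, Csf2rb2, Selp, Cdkn1a, Ddit4, Tubb2b and Aqp1 without AAV-Null 4 and AAV-Osm 5, and Csf2rb2, Ciart, Ccl2, Selp, Ddit4, Tubb2b and Aqp1 without AAV-Null 3 and AAV-Null 4. The other 84 named genes gave 1171 and 751 such values: 1092 and 727 kept their side, 40 and 0 passed the threshold, and 39 and 24 changed sign. None of these sign changes of single genes passed the threshold, and the measures of library composition kept their side throughout (exact permutation p 0.0857 to 1). Where a call below was lost with libraries left out, fewer samples are part of its construction; otherwise the cause was not tested. Depth limits genes near 0.5 CPM, where Scgb3a1 and Selp lie in the AAV-Null libraries.

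The count of 16 changed genes (11 higher, 5 lower) was 53 (24 higher, 29 lower) with DESeq2's Wald test, 170 (79, 91) with limma-voom and quality weights and 42 (18, 24) with 1 surrogate variable. It was 4 (4 higher, 0 lower) at an adjusted p under 0.01 and also 4 (4, 0) against a minimum fold of 1.5, both stricter by construction. Without AAV-Null 4 and AAV-Osm 5 it was 13 with 3 lower. With 1 library left out it ran from 4 (AAV-Null 2 or AAV-Osm 2) to 11 (AAV-Null 3), with 4 to 7 higher and 0 to 6 lower. The 23 lists called became 8 without AAV-Null 4 and AAV-Osm 5, 15 without AAV-Null 3 and AAV-Null 4, 0 with an estimated correlation and 0 with fry, and 15 (AAV-Null 4) to 25 (AAV-Osm 4) with 1 library left out. Named genes that passed only in an alternative were 3 with 1 surrogate variable (Nes, Per1 and Cxcl9), 10 with DESeq2 (the same 3 with Arntl, Nfil3, Sdf2l1, Serpina3g, Serpinh1, Slc39a8 and Txnip), 25 with quality weights (the same 10 with Cfb, Dnaja1, Errfi1, Fbxo32, Hsp90aa1, Hspb1, Hyou1, Il6st, Manf, Meox1, Myom3, Nppb, Pdia4, Serpina3n and Tcap), 1 without AAV-Null 3 and AAV-Null 4 (Cfb) and 1 without AAV-Null 4 and AAV-Osm 5 (Arntl).

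Sign changes of log2 fold changes follow by setting. With quality weights they were 0.12 for Timp1, -0.41 for Postn, -0.17 for Acta1, -0.049 for Eda2r, -0.13 for Runx1, -0.16 for Ppargc1a, 0.014 for Rps2, 0.34 for Rps15, -0.051 for Rora and -0.21 for Bhlhe40. With total counts they were -0.011 for Postn, -0.0023 for Eda2r and -0.031 for Ppargc1a, with 1 surrogate variable -0.049 for Runx1, -0.15 for Ppargc1a and -0.036 for Rora, and with length and GC offsets -0.019 for Postn, -0.0099 for Eda2r, -0.052 for Runx1, -0.011 for Ppargc1a and 0.073 for Rps15. Without AAV-Null 4 and AAV-Osm 5 they were -0.30 for Postn, -0.11 for Acta1, -0.13 for Eda2r, -0.054 for Runx1, -0.036 for Ppargc1a, 0.28 for Rps15, 0.032 for Col4a1 and -0.28 for Bhlhe40. Without AAV-Null 3 and AAV-Null 4 they were 0.33 for Timp1, -0.28 for Postn, -0.42 for Acta1, -0.086 for Eda2r, -0.068 for Runx1, -0.012 for Cpt1b, -0.20 for Ppargc1a, 0.080 for Rps2, 0.39 for Rps15 and -0.067 for Rora.

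With 1 library left out, the log2 fold changes that changed sign ran from -0.18 to 0.19 for Postn, -0.088 to 0.50 for Acta1, -0.18 to 0.046 for Trim63, -0.10 to 0.17 for Eda2r, -0.11 to 0.16 for Runx1, -0.11 to 0.12 for Ppargc1a, -0.38 to 0.17 for Rps15, -0.14 to 0.0087 for Cryab, -0.033 to 0.21 for Rora, -0.090 to 0.47 for Bhlhe40, -0.066 to 0.74 for C3 and -0.11 to 0.55 for Hp.

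For the gene lists the values are adjusted p. Calls lost with an estimated correlation were 0.310 for epicardial markers, 0.701 for ribosomal proteins, 0.416 for collagens, 0.276 for heat shock and the dedifferentiation list, 0.326 for the clock, unfolded protein response, the contractile apparatus, fatty acid oxidation, endothelial markers, nerve markers, neutrophil markers, interferon-stimulated genes, glycolysis, TGF-beta signalling and matrix proteases and crosslinkers, 0.515 for fibroblast markers, chemokines, acute-phase proteins, the cell cycle list and the NF-kappaB list, 0.751 for oxidative phosphorylation and 0.630 for immediate early genes. Those lost with fry were 0.314 for epicardial markers, heat shock, unfolded protein response, the contractile apparatus, fatty acid oxidation, endothelial markers, nerve markers, neutrophil markers, interferon-stimulated genes, glycolysis and matrix proteases and crosslinkers, 0.702 for ribosomal proteins, oxidative phosphorylation and immediate early genes, 0.329 for collagens, the clock, TGF-beta signalling and the cell cycle list, 0.0718 for the dedifferentiation list, 0.538 for fibroblast markers, chemokines and the NF-kappaB list and 0.569 for acute-phase proteins, and fry turned the direction of atrophy genes (0.962). With 1 surrogate variable, calls were lost at 0.0611 for the contractile apparatus, 0.0719 for fatty acid oxidation, 0.0592 for endothelial markers and acute-phase proteins, 0.0691 for chemokines, 0.0845 for glycolysis and the NF-kappaB list and 0.0663 for the cell cycle list, gained at 0.0328 for glucocorticoid-responsive genes, and the direction turned at 0.882 for gp130-STAT3 targets and the cardiac stress programme.

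Without AAV-Null 4 and AAV-Osm 5, calls were lost at 0.172 for collagens, 0.265 for the clock, 0.624 for fibroblast markers, 0.0892 for fatty acid oxidation, 0.122 for endothelial markers and neutrophil markers, 0.284 for chemokines, 0.387 for nerve markers, 0.141 for interferon-stimulated genes, 0.0680 for glycolysis and TGF-beta signalling, 0.464 for matrix proteases and crosslinkers and 0.243 for the cell cycle list, and the direction turned at 0.141 for ribosomal proteins, 0.691 for gp130-STAT3 targets, 0.746 for the cardiac stress programme, 0.464 for oxidative phosphorylation and 0.167 for macrophage markers. Without AAV-Null 3 and AAV-Null 4, calls were lost at 0.524 for the clock, 0.630 for fibroblast markers, 0.232 for fatty acid oxidation and matrix proteases and crosslinkers, 0.168 for endothelial markers, nerve markers and TGF-beta signalling, 0.627 for chemokines, 0.234 for neutrophil markers, 0.302 for interferon-stimulated genes and 0.849 for the cell cycle list, gained at 0.0189 for myofibroblast markers and 0.0289 for complement and coagulation, and the direction turned at 0.000178 for ribosomal proteins, 0.965 for gp130-STAT3 targets, 0.818 for the cardiac stress programme, 0.20 for oxidative phosphorylation and 0.0189 for macrophage markers, so that ribosomal proteins and macrophage markers were called upward there. With length and GC offsets, calls were lost at 0.331 for ribosomal proteins, 0.0755 for chemokines and 0.108 for the NF-kappaB list, and the direction turned at 0.669 for atrophy genes and 0.606 for oxidative phosphorylation. With a minimum mean of 1 CPM, the call was lost at 0.126 for acute-phase proteins, and the direction turned at 0.958 for the cardiac stress programme.

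With 1 library left out, the adjusted p of lists whose call or direction changed ran from 3.18e-12 to 0.664 for ribosomal proteins, 0.000129 to 0.348 for fibroblast markers, 0.00109 to 0.118 for endothelial markers, 0.000221 to 0.289 for chemokines, 0.00176 to 0.671 for acute-phase proteins, 0.0179 to 0.486 for glucocorticoid-responsive genes, 0.0250 to 0.494 for myofibroblast markers, 0.0250 to 0.997 for complement and coagulation, 0.121 to 0.991 for gp130-STAT3 targets, 0.253 to 0.976 for the cardiac stress programme, 0.505 to 0.959 for atrophy genes, 0.000351 to 0.0568 for nerve markers, 0.000384 to 0.140 for neutrophil markers, 0.0173 to 0.210 for glycolysis, 0.00712 to 0.140 for TGF-beta signalling, 4.70e-06 to 0.686 for oxidative phosphorylation, 0.00151 to 0.487 for macrophage markers, 6.57e-07 to 0.277 for immediate early genes, 0.000762 to 0.134 for matrix proteases and crosslinkers, 0.000773 to 0.118 for the cell cycle list and 0.00177 to 0.229 for the NF-kappaB list.

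Counts of genes higher and lower adjusted over the list alone moved in further lists. With all libraries they were 0 and 2 for the dedifferentiation list, 0 and 1 for fibroblast markers, 3 and 0 for fatty acid oxidation, 0 and 1 for endothelial markers, 2 and 2 for chemokines, 2 and 3 for glucocorticoid-responsive genes, 0 and 1 for myofibroblast markers, 0 and 0 for nerve markers, 0 and 0 for TGF-beta signalling, 0 and 0 for immediate early genes, 0 and 1 for matrix proteases and crosslinkers and 0 and 1 for the NF-kappaB list. Leaving out AAV-Null 4 and AAV-Osm 5 moved fibroblast markers to 0 and 0, fatty acid oxidation to 2 and 0, endothelial markers to 1 and 2, glucocorticoid-responsive genes to 3 and 6, myofibroblast markers to 0 and 0, nerve markers to 0 and 1, TGF-beta signalling to 0 and 2, immediate early genes to 0 and 3, matrix proteases and crosslinkers to 2 and 3 and the NF-kappaB list to 0 and 3. Leaving out AAV-Null 3 and AAV-Null 4 moved the dedifferentiation list to 0 and 3, fibroblast markers to 0 and 0, endothelial markers to 2 and 3, chemokines to 1 and 1, myofibroblast markers to 1 and 3, immediate early genes to 0 and 1, matrix proteases and crosslinkers to 0 and 3 and the NF-kappaB list to 0 and 3. Neither moved the counts of ribosomal proteins, collagens, the oncostatin M receptor complex and cytokine family, atrophy genes, neutrophil markers, interferon-stimulated genes, glycolysis, oxidative phosphorylation, macrophage markers and the cell cycle list.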

Other observations

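Among the tests in this part, the time of day and liver tests were chosen after the result was seen, while the length and GC test of the clock genes and the splits of the samples were written down before their results were seen. Camera also called lists of other cell types and pathways in which 0 members passed over all genes. Schwann and nerve markers were negative in 10 of 10 tested genes (median -0.28, camera adjusted p = 0.00255) and neutrophil markers in 9 of 9 (median -0.25, 0.00389), with an adjusted p = 0.326 for both with an estimated correlation. Interferon-stimulated genes were negative in 29 of 38 (median -0.19, camera adjusted p = 0.00265), and TGF-beta signalling genes and targets in 20 of 29 (median -0.15, 0.0408), again with an adjusted p = 0.326 for both with an estimated correlation. Genes of glucose uptake and glycolysis were positive in 21 of 30 (median 0.07, camera adjusted p = 0.0421; adjusted p = 0.326 with an estimated correlation). Nuclear genes of oxidative phosphorylation were negative in 54 of 75 (median -0.12, camera adjusted p = 0.00658, and adjusted p = 0.751 with an estimated correlation), but their direction turned upward with length and GC offsets (0.606), without AAV-Null 4 and AAV-Osm 5 (0.464) and without AAV-Null 3 and AAV-Null 4 (0.20). Their median was also above 0 with limma-voom and quality weights (0.059) and without AAV-Null 4 alone (0.0040). Macrophage and monocyte markers were not called (31 tested, median -0.12, camera adjusted p = 0.150), and their direction depended on the libraries. They were called downward without AAV-Null 1 (0.00151), AAV-Null 2 (0.00469) or AAV-Osm 1 (0.00246) and upward without AAV-Null 3 and AAV-Null 4 (median 0.24, 0.0189), and the direction also turned without AAV-Null 4 (0.274) and without AAV-Null 4 and AAV-Osm 5 (0.167); over the camera alternatives the adjusted p ran from 0.00151 to 0.787. The other 5 lists of this paragraph were not called without AAV-Null 4 and AAV-Osm 5 (0.0680 to 0.387). Adjusted over each of these lists alone, 0 members passed with all libraries, while without AAV-Null 4 and AAV-Osm 5 1 nerve marker and 2 TGF-beta genes were lower.

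Immediate early genes, cell cycle genes and genes of the NF-kappaB and TNF response were also called downward. Of 25 immediate early genes 17 were negative and 0 passed over all genes or adjusted over the list alone (median -0.24, camera adjusted p = 0.00377; adjusted p = 0.630 with an estimated correlation). Of 28 cell cycle and proliferation genes 21 were negative and 0 passed either way (median -0.17, camera adjusted p = 0.00600; adjusted p = 0.515 with an estimated correlation). Among 22 NF-kappaB and TNF response genes 12 were negative and 1 fell, Ccl2, which was also the member lower adjusted over the list alone (median -0.05, camera adjusted p = 0.0270; adjusted p = 0.515 with an estimated correlation). Without AAV-Osm 2 the camera adjusted p was 0.277 for the immediate early list and 0.229 for the NF-kappaB list, and without AAV-Null 4 it was 0.118 for the cell cycle list. Over the camera alternatives it ran from 4.98e-08 to 0.630 for immediate early genes, 0.00177 to 0.515 for the NF-kappaB list and 0.000773 to 0.849 for the cell cycle list. Of the immediate early genes 3 were lower adjusted over the list alone without AAV-Null 4 and AAV-Osm 5 and 1 without AAV-Null 3 and AAV-Null 4, and 3 of the NF-kappaB list were lower in each case.

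Txnip, which binds thioredoxin and restrains glucose uptake, did not pass in edgeR, at 230 ± 39.9 CPM in AAV-Null (SD, n = 4) and 439 ± 86.5 CPM in AAV-Osm (SD, n = 5), a log2 fold change of 0.93 (SE 0.18, edgeR adjusted p = 0.114); it passed in DESeq2 and in limma-voom with quality weights. The ribosomal protein list had a median of -0.19, of -0.04 with length and GC offsets, and above 0 with quality weights (0.12), without AAV-Null 4 (0.040), without AAV-Null 4 and AAV-Osm 5 (0.10) and without AAV-Null 3 and AAV-Null 4 (0.18), and its list mean had an exact permutation p of 0.524.

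Of the 19 clock genes tested, 13 had a positive and 6 a negative log2 fold change. After these values had been seen, 15 were set in arms by their known phase, 10 with E-box or D-box elements (Per1, Per2, Per3, Dbp, Tef, Hlf, Ciart, Nr1d1, Nr1d2 and Cry2, all positive) against 5 (Arntl, Clock, Npas2, Nfil3 and Cry1, all negative), leaving out 4 (Bhlhe41 at 0.59, Bhlhe40 at 0.34 and Rora at 0.12 among them), so the split of signs is no test. The difference between the arms per library was 0.95 ± 0.38 in AAV-Null and 2.36 ± 0.40 in AAV-Osm (mean ± SD), with the lowest AAV-Osm library at 1.71 and the highest AAV-Null library at 1.35. The tables argue against a trend on length and GC content, since the group difference after correction was 1.02 times that before (1.43 against 1.41). A shifted clock phase is a hypothesis. A different time of day at tissue collection or an effect of the treatment on the clock cannot be told apart as its source, since the labels give no collection times. The exact permutation p of 0.0159 between the groups, the smallest possible, rests on arms chosen with the values known. By the same exact test the mean of the whole clock list, fixed beforehand, gave p = 0.127.

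Liver-type transcripts varied widely over libraries. Alb ran from 0.272 CPM in AAV-Osm 2 to 70.8 in AAV-Null 3, and Apoa1 from 0.272 to 26.5 in the same libraries. The 29 listed genes of a set of 31 rose and fell together (median pairwise correlation across libraries 0.940, highest of 1000 random lists 0.210), which is consistent with liver RNA in some of the libraries; 3 of them had at least 1 CPM in the library with the lowest sum and so may be expressed in the heart, and 8 stand in other fixed lists. Whether the treatment moved them stays open: the difference of the list mean was -0.86 (95% interval -3.50 to 1.79, exact permutation p = 0.476). Without AAV-Null 3 and AAV-Null 4, which held the most, 16 genes passed in edgeR, 9 of them shared with the fit to all libraries.

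Other splits of the 9 libraries into 4 and 5 were tried, 100 in all with the real split included. As many changed genes as the real 16 came from 3 of the 100 splits (highest other 1482), as many higher genes as 11 from 3 (highest other 903) and as many lower genes as 5 from 3 (highest other 710), under 5% of the splits in each case. The other splits that reached these counts mixed the groups and called far more genes. The splits therefore cannot exclude that such a structure fell in part along the groups by chance. For the 23 lists called, 6 of the 100 splits gave as many (highest other 29), and chance cannot be excluded. Among these, AAV-Osm 1, 2, 3 and 5 (23 lists) and AAV-Osm 2, 3, 4 and 5 (24 lists) stood against the rest. Those splits kept all AAV-Null libraries together and so most of the real contrast. The other splits that reached 23, the one with 29 included, had both groups on each side. No split called fewer than 2 lists, so camera's call of a single list is weak evidence here. The split with 1075 genes set AAV-Null 1, AAV-Null 2, AAV-Osm 1 and AAV-Osm 5 against the rest. That with 1482 genes set AAV-Null 3, AAV-Null 4, AAV-Osm 2 and AAV-Osm 3 against the rest. Apart from the side of AAV-Osm 4 these are the same contrast, along the first principal component. The libraries set apart in the latter split had positive scores on it (9.24 to 44.8) and all others negative ones (-38.5 to -3.41). Its gene loadings had a Spearman correlation of 0.38 with GC content and -0.26 with exon length. The labels do not name this structure of the samples.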
